A study of Mus musculus with 4 samples.

How the data were processed

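Messenger RNA was measured in single cells of 4 libraries of mouse T cells, 1 per group. Per the labels' protocols, Hepa1-6 cells, a mouse hepatoma line, were injected under the skin and mice were killed on day 23. The labels give that day for the tumor libraries and no day for the lymph node library. CD4 cells were enriched on microbeads and then sorted by flow cytometry. The sort used the YFP that is made together with Cre from the Foxp3 locus, so that YFP-positive cells stood for regulatory T cells (Treg) and YFP-negative cells for conventional T cells (Tconv). The groups were tumor Treg cells of mice with Foxp3-driven Cre alone (WT), tumor Treg cells of a library titled Tbx21 KO, tumor Tconv cells of WT mice, and Treg cells from tumor-free lymph nodes (LN) of WT mice. The series design places the KO cells in mice that also carry floxed Tbx21 alleles, while the genotype label of that library names the Foxp3-Cre mice alone. It is therefore called the library labelled Tbx21 KO Treg. Cells of several mice were pooled in each library, so no library has a replicate. Cartridges of the BD Rhapsody whole transcriptome system were loaded with 80000 cells to capture 50000 to 60000 per sample, per the labels' protocols.

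The values used were counts of unique molecular identifiers (UMIs) per gene and barcode, as deposited by the authors in 1 sparse matrix per library with gene symbols. All values were whole numbers of at least 1, and no barcode had fewer than 1811 UMIs, so the barcodes had been filtered before deposit. The submitters' processing notes name Seurat 5.0.2 and the genome builds GRCm39 and mm10, without saying which build was used for which step. The aligner, the counting tool and the way cell barcodes were called are not given in the sources used here. No coordinates were used, and genes are named by the symbols of the files. The libraries list 28025 (LN Treg), 28469 (Tconv), 30083 (labelled Tbx21 KO Treg) and 29179 (WT tumor Treg) genes, 26112 of them in all 4 and 31549 in any.

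Barcodes were kept with at least 500 UMIs, at least 250 genes and at most 20% mitochondrial UMIs. This left 52314 of 52527 LN Treg barcodes, 52010 of 52827 Tconv barcodes, 55088 of 63717 barcodes of the library labelled Tbx21 KO Treg and 46361 of 46964 WT tumor Treg barcodes. The mitochondrial limit removed 13.5% of the barcodes of the library labelled Tbx21 KO Treg and between 0.406% and 1.55% of those of the other libraries. No doublet caller was run. Doublets were handled by leaving out clusters of other cell types and by an alternative without cells that had 3 or more UMIs of non-T markers and without the 2% of cells with most UMIs. The markers counted there omit Xbp1, Krt8, Krt18, Itgax, Pecam1, Ccr9, Igkc and Ighm, which T cells can also express or carry. Of the T cells kept below, 14771 of 40829 in the library labelled Tbx21 KO Treg had 3 or more such UMIs. The numbers were 2704 of 45562 in WT tumor Treg, 1625 of 51232 in Tconv and 1670 of 52104 in LN Treg.

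For clustering, 6000 cells per library were drawn at random and scaled to their totals. The 2000 most variable genes, without the Th1 and the adenosine lists, gave 30 principal components, a graph of 20 neighbours and 18 Leiden clusters at resolution 1. All other cells took the most common cluster among their 15 nearest clustered cells. A cluster was left out as non-T where its summed T-cell markers were below 1/3 of the median cluster, a threshold set after the clusters were seen. These were cluster 7 (hepatoma-like), cluster 14 (macrophage-like) and cluster 18 (plasmacytoid dendritic-like), whose leading genes were markers of those types. The remaining T cells numbered 52104 (LN Treg), 51232 (Tconv), 40829 (labelled Tbx21 KO Treg) and 45562 (WT tumor Treg). Cluster names come from markers fixed beforehand, except that cluster 13 has none of them among its 10 leading genes and was joined to cluster 1 after the data were seen. Clusters 5 and 8 stayed unnamed, and cluster 8, with 3 erythroid markers among its leading genes, was kept as T cells because its T-cell markers lay above the threshold. Clusters 1 and 13 were taken as Treg-like only for the comparison of both tumor Treg libraries, and LN clusters 3 and 4 are given by number.

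UMIs were summed over the T cells of each library and divided by the total of those cells, on the usual scale of counts (CPM). Each CPM has an exact Poisson 95% interval, each log2 ratio of CPM an exact conditional (Clopper-Pearson) 95% interval and each share of cells an exact binomial (Clopper-Pearson) 95% interval. Where a count was 0 the limit given is 3 counts of the total. All cover counting error only, and with 1 library per group no test was run and no p-value was computed. The comparisons were labelled Tbx21 KO Treg over WT tumor Treg, WT tumor Treg over LN Treg, and WT tumor Treg over WT tumor Tconv. A gene was counted as apart at 2-fold or more with at least 25 CPM in the higher library. The median log2 ratio of a gene list was placed among 10000 random lists of the same size matched on mean expression in 20 bins. The percentile describes these libraries only. A list member was measured with at least 10 UMIs over both libraries and called higher or lower from 1.5-fold. Shares of cells with a UMI were taken after each cell was thinned at random to 2000 UMIs, leaving out 12 (LN Treg), 0 (Tconv), 2 (labelled Tbx21 KO Treg) and 153 (WT tumor Treg) shallower cells.

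The 20 lists were Treg identity, Th1 programme, ectonucleotidase and adenosine, effector Treg, inhibitory receptors, naive and central memory, Th2, Th17, Tfh, type I interferon response, interferon gamma response, cell cycle, glycolysis and hypoxia, lipid metabolism, immediate early and heat shock, TCR signal, chemokine and homing receptors, cytotoxic, cytokines, and sex chromosome genes. Named genes are the 12 with the highest and the 12 with the lowest ratio per comparison among genes with at least 25 CPM and a UMI in at least 5% of T cells of the higher library. T cell receptor, immunoglobulin, mitochondrial, ribosomal protein, histone, haemoglobin, Xist and Y-linked genes and predicted models were left out. Genes over 10 times higher in non-T cells than in T cells of either library were also left out and counted apart. Named besides are 2 to 4 members per list with the highest CPM among those 1.5-fold apart, and always Tbx21, Foxp3, Entpd1, Cxcr3, Ifng and Nt5e. Other genes in the text lie outside this rule. They are markers of cell types, members of the lists tested in cluster 14, sex chromosome genes or genes used to choose cells, and which of them to name was decided after their values were seen, as was which genes to give for single clusters.

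The code was tested on simulated counts drawn from the real means and library totals with 200 changed genes. They hold counting error only and no variation between libraries or mice, so at this depth the outcome was expected and says nothing about power. In each of the 3 comparisons, 100% of genes changed 4-fold and 100% of those changed 2.8-fold passed the 2-fold limit at 25 CPM, and 0 unchanged genes did. These runs covered 5465, 5787 and 5451 genes at 25 CPM for the KO-labelled, LN and Tconv comparisons. The intervals held the true ratio for 94.7%, 95.4% and 95.2% of genes. Alternatives were all cells passing the filter, T cells with a Foxp3 UMI (Tconv: without), no mixed droplets, at least 1000 UMIs, at most 10% mitochondrial UMIs, TMM scaling, totals without mitochondrial and ribosomal protein genes, per-cell means, cells thinned to 1000 or 4000 UMIs or not thinned, equal cluster weights, a minimum of 10 or 100 CPM, cluster resolutions 0.5 and 2 and clustering on all variable genes. Equal cluster weights mean that a cluster weighed the same in both libraries, by its smaller cell number, not that clusters weighed alike. Only T cell clusters with at least 50 cells in each library entered. In the KO-labelled pair 2047 of these 4277 cells lay in the cycling cluster 9 and 1056 in the CD8-like cluster 12. Added after the data were seen were clusters 1, 3, 4 and 13 only, the T cells without cluster 5, 8 or 12 or without cells with an Mcpt8 UMI, and Foxp3 UMI cells for the Entpd1 shares. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.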

Results

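Single-cell UMI counts were available for 4 libraries of mouse T cells, from tumors of Hepa1-6, a mouse hepatoma line grown under the skin, and from lymph nodes. They were regulatory T cells (Treg) from tumors of WT mice, Treg cells from tumors in a library labelled Tbx21 KO, conventional CD4 T cells (Tconv) from WT tumors, and Treg cells from tumor-free lymph nodes (LN) of WT mice. Each group had 1 library of cells pooled from several mice, so there are no replicates, and all intervals cover counting error only. The libraries held 321973022 UMIs over 52527 barcodes (LN Treg), 371792179 over 52827 (Tconv), 722822111 over 63717 (labelled Tbx21 KO Treg) and 301732348 over 46964 (WT tumor Treg). After the filters, T cells made up 99.6% of LN Treg, 98.5% of Tconv and 98.3% of WT tumor Treg cells but 74.1% of cells of the library labelled Tbx21 KO Treg. Of the latter T cells 14771 of 40829 had 3 or more UMIs of non-T markers, against 2704 of 45562 in WT tumor Treg. The T cells had a median of 5240, 5750, 5794 and 5068 UMIs in the LN Treg, Tconv, labelled Tbx21 KO Treg and WT tumor Treg libraries. All levels below are over these T cells, as pooled CPM (the UMIs of a gene over all UMIs of these cells, scaled to a common total) with exact Poisson 95% intervals.

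Tbx21 encodes T-bet, the lineage factor of Th1 cells and the gene the KO label names. It stood at 20.7 CPM (20.2 to 21.2) in the library labelled Tbx21 KO Treg, 118 CPM (116 to 119) in WT tumor Treg, 135 CPM (133 to 136) in Tconv and 3.39 CPM (3.19 to 3.60) in LN Treg cells. The labels do not give the deleted exons, and UMIs from a part of the transcript outside them check nothing, so the 20.7 CPM is no measure of deletion. Foxp3, the lineage factor of Treg cells and the gene that drives the sorted YFP, stood at 52.3 CPM (51.5 to 53.1) in WT tumor Treg and 70.2 CPM (69.3 to 71.2) in LN Treg cells. Tconv cells had 0.370 CPM of Foxp3 (0.310 to 0.439), and the library labelled Tbx21 KO Treg had 6.70 CPM, far below the other Treg libraries. Every direction drawn from that library below rests on its label.

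Shares of cells with a UMI followed the same order at 2000 UMIs per cell. Foxp3 was seen in 12.9% of LN Treg, 10.4% of WT tumor Treg, 1.68% of labelled Tbx21 KO Treg and 0.082% of Tconv cells, and without thinning in 29.5%, 23.8%, 4.13% and 0.211%. Tbx21 was seen in 0.549%, 20.3%, 4.20% and 22.6% and Entpd1 in 5.49%, 17.6%, 6.57% and 12.5% of LN Treg, WT tumor Treg, labelled Tbx21 KO Treg and Tconv cells. Cxcr3 was seen in 5.18%, 26.9%, 0.377% and 17.9% in the same order, and in 10.5%, 50.3%, 0.899% and 37.2% without thinning. Hepatoma-like cells of the library labelled Tbx21 KO Treg, which should lack these T cell transcripts, gave a background of 0.234% for Foxp3, 0.855% for Tbx21, 0.045% for Cxcr3 and 0.603% for Entpd1 at 2000 UMIs. In 101 hepatoma-like cells each of WT tumor Treg and Tconv the shares were 0.990% and 3.96% for Tbx21, 4.95% and 1.98% for Cxcr3 and 4.95% and 1.98% for Entpd1, with limits up to 11.2%. LN Treg had no hepatoma-like cells. Its 193 macrophage-like cells gave 0.518% for Tbx21 (0.013 to 2.85), 4.15% for Cxcr3 (1.81 to 8.00) and 10.4% for Entpd1 (6.45 to 15.6). They also held Ikzf2 in 34.7% and Foxp3 in 5.70%, so they are no background free of T cell RNA. They cannot tell whether the LN shares of Tbx21, Cxcr3 and Entpd1 exceed a background. Unthinned, at a median of 20231 UMIs, the background of the library labelled Tbx21 KO Treg was 1% for Foxp3, 4.07% for Tbx21, 0.171% for Cxcr3 and 5.51% for Entpd1. The unthinned T cells showed Tbx21 in 1.44% of LN Treg, 41.0% of WT tumor Treg, 11.7% of labelled Tbx21 KO Treg and 48.2% of Tconv cells, and Entpd1 in 13.8%, 37.7%, 18.3% and 29.8%.

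**Figure D1:**
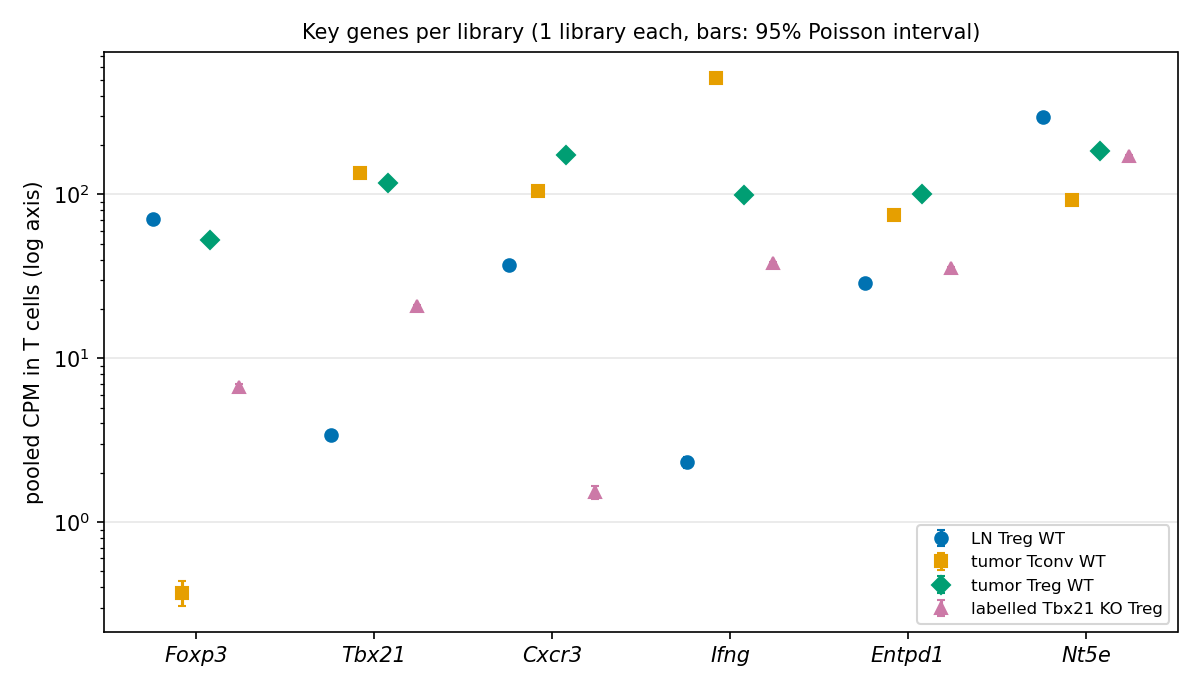
Pooled CPM of 6 genes in the T cells of each library on a log axis, with 1 point per library and bars for the exact Poisson 95% interval. Foxp3 lay at 52.3 CPM in WT tumor Treg but 6.70 CPM in the library labelled Tbx21 KO Treg, and Entpd1 was highest in WT tumor Treg cells at 99.8 CPM.

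The comparison of both tumor Treg libraries asks what differs in Treg cells of the tumor when Tbx21 is deleted from Foxp3-expressing cells, with CD39 named in the series title. In the library labelled Tbx21 KO Treg the Th1 genes were low. Cxcr3, the chemokine receptor for interferon-induced ligands, was at 1.52 CPM against 173 CPM in WT (log2 ratio −6.83, exact interval −6.96 to −6.70). Tbx21 itself was lower by a log2 ratio of −2.50 (−2.54 to −2.46). Entpd1, which encodes the ectonucleotidase CD39, was at 35.4 CPM against 99.8 CPM (log2 −1.49, −1.53 to −1.46). The type 2 cytokine genes were high instead, with Il13 at 517 CPM against 3.06 CPM (log2 7.40, 7.30 to 7.50), Il5 at 271 CPM against 5.14 CPM and Il4 at 134 CPM against 2.51 CPM.

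Of 5820 genes at 25 CPM or more, 631 were at least 2-fold apart, 255 higher and 376 lower in the library labelled Tbx21 KO Treg. The median log2 ratio of all these genes was −0.15, and with TMM scaling, which shifts every ratio of this pair by 0.20 upward, it was 0.07 and the split was 377 higher against 238 lower. Among the 631, 60 seen in at least 5% of T cells were over 10 times higher in non-T cells. In cells with a Foxp3 UMI (1688 and 10863 cells) 371 genes were 2-fold apart, and 355 of the 631 kept the same direction at 2-fold there. Taking only clusters 1 and 13, the Treg-like clusters that hold 37348 WT cells (cluster 1) and 5054 cells of the labelled Tbx21 KO library (cluster 13), left 355 genes, and 319 of the 631 were still 2-fold apart there in the same direction. This set also takes in clusters 3 and 4, which add 7 and 11 cells of the labelled Tbx21 KO library and 5 and 32 of WT. The clusters were formed on these same data with most Treg genes kept. Gzmb, Il10, Gzma, Itgae, Klrg1 and Areg are among the leading genes of cluster 13. Ratios of such genes in clusters 1 and 13 are therefore not independent of how cells were grouped. With all cells that passed the filter, hepatoma-like and macrophage-like cells included, 1840 genes were 2-fold apart.

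The 12 genes with the highest ratio in the library labelled Tbx21 KO Treg were Il13, Bex1, Npy, Lpar3, Il17rb, Crabp2, Olr1, Il4, Il5, Cdh17, Igfbp7 and Lgals7, with log2 ratios from 4.89 to 7.40. Il17rb encodes a receptor chain for interleukin 25 and reached 60.3 CPM against 0.851 CPM. Crabp2, a retinoic acid binding protein, reached 224 CPM against 3.20 CPM, and Npy, the neuropeptide Y precursor, 140 CPM against 1.57 CPM. Il13, Npy, Crabp2, Il5, Bex1, Igfbp7 and Il4 are also leading genes of cluster 5, which held 18473 cells of this library and 20 of WT. In Foxp3 UMI cells the 12 ratios lay between 3.53 and 6.58, and in clusters 1 and 13 between 1.78 and 5.59. These ratios are not shown to be free of stray RNA. At 2000 UMIs Il13 was seen in 7.76% of Foxp3 UMI cells and 4.00% of cells of clusters 1, 3, 4 and 13 of the library labelled Tbx21 KO Treg. Its hepatoma-like, plasmacytoid dendritic-like and macrophage-like cells showed Il13 in 3.43%, 6.51% and 8.09%. The 12 lowest were Cxcr3, Il12rb2, Ttn, Lrrc32, Ikzf2, Foxp3, Ctsw, Raet1e, Itgb8, Serpina3f, Ifi209 and Ipcef1, from −6.83 to −2.58. Il12rb2, a chain of the interleukin 12 receptor, was at 0.831 CPM against 44.7 CPM. Lrrc32, which holds latent TGF-beta on the Treg surface, was at 17.1 CPM against 184 CPM, Ikzf2 (Helios) at 149 CPM against 1341 CPM and Itgb8, an integrin chain that activates TGF-beta, at 23.7 CPM against 156 CPM. In Foxp3 UMI cells the log2 ratio of Lrrc32 and that of Ikzf2 were both −1.39 and that of Itgb8 was −1.34.

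The Th1 programme list had a median log2 ratio of −1.24, lower than all 10000 matched random lists (percentile 0), with 14 of 19 members lower and 2 higher. Nkg7, a cytotoxic granule protein, had a ratio of −1.74 (−2.99 in Foxp3 UMI cells), the chemokine genes Ccl4 and Ccl3 −1.18 and −1.24 (−2.73 and −2.56), and Hopx −1.40 (−0.17). Ifng was at 38.0 CPM against 99.3 CPM (−1.39), and at −2.65 in Foxp3 UMI cells. The list median was −1.66 in Foxp3 UMI cells and −1.63 in clusters 1 and 13. Of 16 type I interferon response genes 12 were lower (median −1.39, percentile 0), among them Isg20 at −1.89 (−1.08 in Foxp3 UMI cells) and Ifi27l2a at −1.28, and the median was −0.92 in Foxp3 UMI cells and −0.53 in clusters 1 and 13. Of 16 interferon gamma response genes 9 were lower and 1 higher (median −0.70, percentile 0.01). Ifngr1, the receptor chain, was at −1.98 (−1.21 in Foxp3 UMI cells) and Gbp7 at −1.37 (−0.66), whereas Igtp, at −1.25, was at 0.02 in clusters 1 and 13, where the list median turned to 0.11.

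Of 8 Th2 genes 6 were higher (median 3.92, percentile 100). Gata3, the Th2 lineage factor, had a ratio of 1.34 and Il1rl1, the interleukin 33 receptor, 2.12. Areg, a growth factor of tissue Treg cells, was the member that was lower, at −0.62, and stood at 0.04 in Foxp3 UMI cells and 0.27 in clusters 1 and 13. Both clusters have Areg among their leading genes, so the last value is not independent of the grouping. The Th2 median was 1.79 in Foxp3 UMI cells and 1.80 in clusters 1 and 13. In both sets the share of cells with Il13 lay within the range of non-T cells of the library labelled Tbx21 KO Treg. Background shares of the other Th2 genes were not taken, so a Th2 gain in Treg-like cells is not separated from stray RNA. Cluster 5, where Il13, Il5 and Il4 lead, also has the basophil marker Mcpt8 among its leading genes, at 72.3 CPM in the library labelled Tbx21 KO Treg but in 2.53% of its cells, against 68.5% with an Il13 UMI, 98% with a Cd4 UMI and 95% with a Cd3e UMI. Without T cells that had an Mcpt8 UMI, a set chosen after the data were seen, Il13 was at 500 CPM against 3.05 CPM and the Th2 median was 3.85. Of 10 Th17 genes 6 were higher and 0 lower (median 2.60, percentile 99.98; 1.21 in clusters 1 and 13), with Tmem176b at 3.45 and Tmem176a at 3.16. Il17a, at 16.2 CPM against 0.569 CPM, had 4.83. Of 9 Tfh genes 5 were higher (median 1.53, percentile 100), led by Il21 at 4.27, with Cd40lg at 1.71 (3.33 and 0.83 in Foxp3 UMI cells). The Tfh median was 0.83 in Foxp3 UMI cells and 0.27 in clusters 1 and 13. Of 16 cytokine genes 7 were higher and 5 lower (median 0.25, but 0.00 in Foxp3 UMI cells and −0.05 in clusters 1 and 13). Il10, which encodes an inhibitory cytokine, was at 416 CPM against 227 CPM (0.88), and at −0.03 when non-T cells were included. Tnfsf11, the RANK ligand, had a ratio of 2.62 (1.65 in Foxp3 UMI cells).

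Of 15 Treg identity genes 9 were lower and 1 higher (median −0.79, percentile 0.01). The interleukin 2 receptor chain gene Il2rb had a ratio of −0.79 and the checkpoint receptor gene Ctla4 −0.59, while the higher member was Il2ra at 0.73, which stood at −0.21 with non-T cells included. This median was −0.20 in Foxp3 UMI cells and −0.04 in clusters 1 and 13. The effector Treg list (7 of 24 higher, 9 lower, median −0.10), the ectonucleotidase and adenosine list (2 of 13 higher, 4 lower, median −0.20) and the cytotoxic list (3 of 11 higher, 3 lower, median −0.15) had medians that reached 0 or turned positive with TMM scaling. In Foxp3 UMI cells the cytotoxic median was −0.85 with 6 of 11 lower and the effector Treg median 0.15, and in clusters 1 and 13 they were −0.31 and 0.30. Members of both lists are among the leading genes of cluster 13, so the medians in these clusters are not independent of the grouping. Among effector Treg genes Icos was at −1.51, Tnfrsf9 at −1.15 and Il1r2, the decoy receptor for interleukin 1, at 2.64, and in Foxp3 UMI cells these stood at −0.76, −0.33 and 1.66. Among adenosine genes Slc29a1, a nucleoside transporter, was at 0.85 and Adora2a, the adenosine receptor, at −0.99 overall but 0.04 in Foxp3 UMI cells. Nt5e, which encodes CD73, was at 171 CPM against 184 CPM, a ratio of −0.10 whose sign turned with TMM scaling, and at 323 CPM against 213 CPM in clusters 1 and 13. Gzma, at 70.4 CPM against 5.86 CPM, was at 3.59, and Ctsw at −2.87.

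Among 12 inhibitory receptor genes 6 were lower and 1 higher (median −0.39, percentile 7.04), with Vsir at −0.94 and Tox at −0.82. Of 16 naive and central memory genes 7 were higher and 4 lower (median 0.44, percentile 99.98), but in clusters 1 and 13 5 and 3 (median 0.06, percentile 88.3). Klf2, a factor for lymphoid recirculation, was at 1.94 and Tcf7 at 1.01 (−0.22 in clusters 1 and 13), whereas Satb1, a chromatin organiser, was at −1.66 (−0.52 in Foxp3 UMI cells). Of 20 chemokine and homing receptors 8 were lower and 2 higher (median −0.40, percentile 2.76), with a median of −0.02 in Foxp3 UMI cells and 0.23 in clusters 1 and 13, among them Ccr2 at −2.27 (−0.66 in Foxp3 UMI cells). The integrin gene Itgae was at −1.29 but at 0.21 in Foxp3 UMI cells and 0.72 in clusters 1 and 13. Itgae is among the leading genes of cluster 13, so the last value is not independent of how cells were grouped. Of 13 TCR signal genes 6 were lower and 3 higher (median −0.49, percentile 1.43; −0.12 and percentile 27.4 in clusters 1 and 13), with Nr4a3 at −1.69, Nr4a1 at −0.75 and Cd69 at 1.15. Of 20 cell cycle genes 5 were lower (median −0.39, percentile 2.67; 0.05 in clusters 1 and 13), with Mki67 at −1.62 and Top2a at −0.80, which was at 0.00 without cluster 5.

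Of 22 glycolysis and hypoxia genes 11 were higher and 1 lower (median 0.59, percentile 100), with Aldoa at 0.64 and Pgk1 at 0.61, and Hif1a at −0.92. Of 15 lipid metabolism genes 7 were higher (median 0.43, percentile 99.94), including Pparg, a fatty acid sensing nuclear receptor, at 2.91 and Fabp5, a fatty acid carrier, at 1.17. Of 17 immediate early and heat shock genes 10 were higher and 0 lower (median 0.67, percentile 100), with Jun at 1.59 and Hspa1b at 1.23. In Foxp3 UMI cells the medians were 0.53 for glycolysis and hypoxia, 0.63 for lipid metabolism and 0.40 for immediate early and heat shock. In the Treg-like clusters they were 0.67, 0.52 and 0.45. Hepatoma and erythroid transcripts were higher as well, and whether stray RNA added to these list medians was not tested. In T cells of the library labelled Tbx21 KO Treg Alb was at 199 CPM against 1.44 CPM in WT, and Hbb-bs at 207 CPM against 9.26 CPM. Its T cells carried Alb, Krt18, Krt8 and Trf at 5.40%, 5.53%, 6.35% and 6.09% of the level in hepatoma-like cells.

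**Figure D2:**
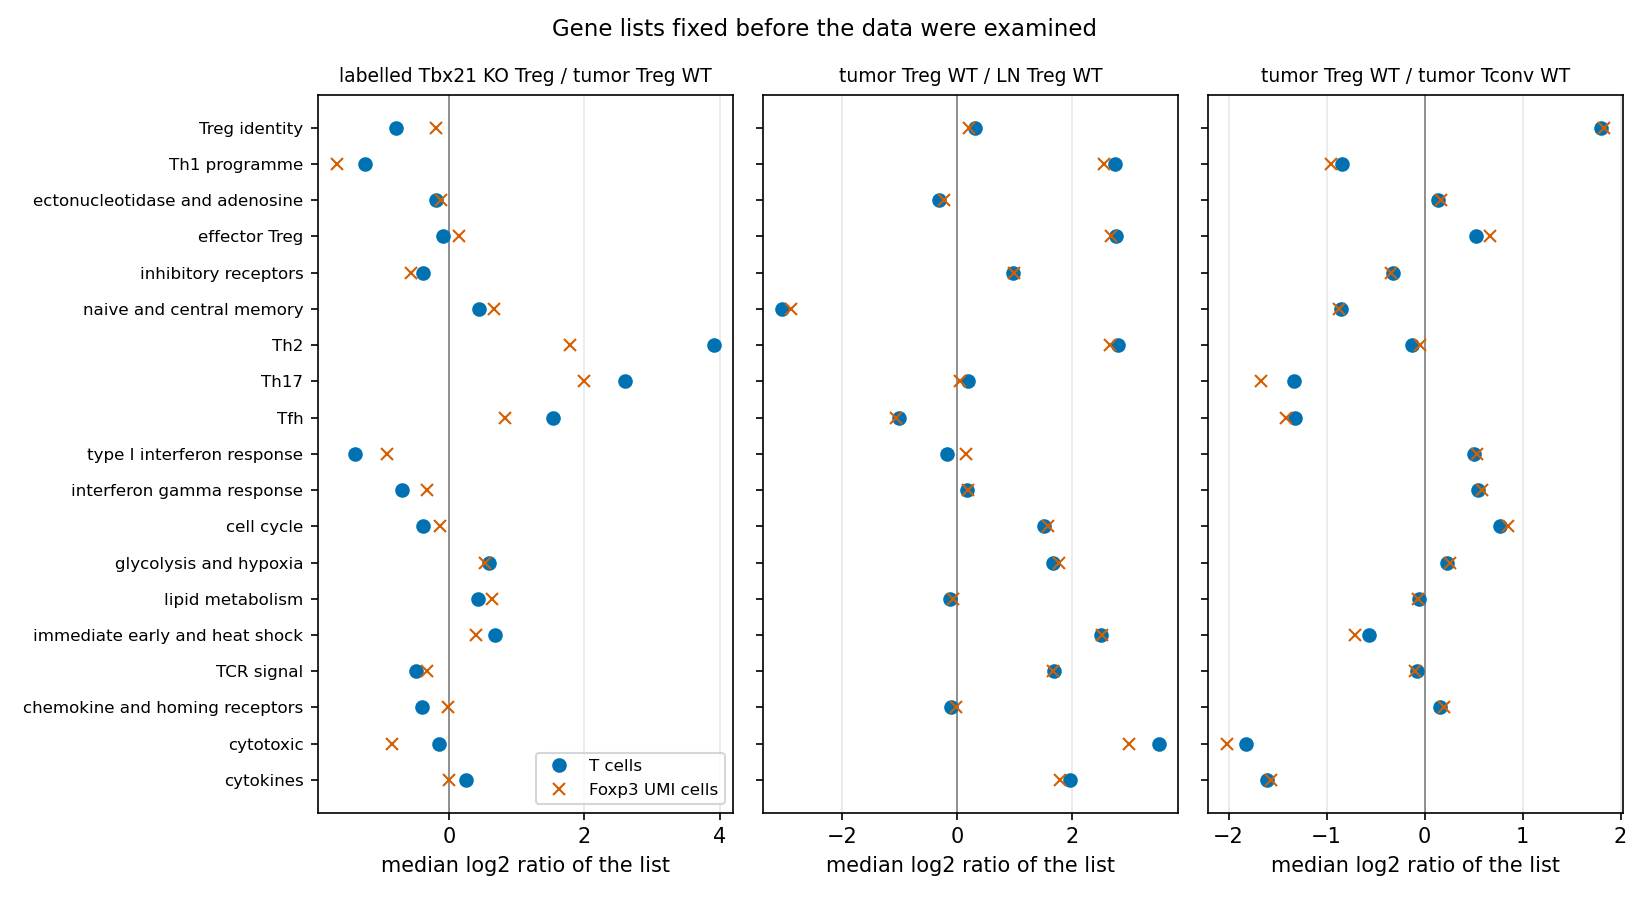
Median log2 ratio of 19 gene lists in the 3 comparisons, with circles for T cells and crosses for T cells with a Foxp3 UMI (in the Tconv library, cells without). In the KO-labelled comparison the Th1 programme lay at −1.24 and Th2 at 3.92, and the small medians of the effector Treg, adenosine and cytotoxic lists there reached 0 or turned sign with TMM scaling.

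The libraries were also compared over clusters 1 and 13, where 5054 of 5536 cells of the library labelled Tbx21 KO Treg lay in cluster 13 and 37348 of 37364 WT cells in cluster 1, so mix and level are not separated. Foxp3 was at 37.7 CPM (35.6 to 39.9) in the library labelled Tbx21 KO Treg and 60.9 CPM (59.9 to 62.0) in WT, a ratio of 0.619 (0.582 to 0.657). Entpd1 was at 62.5 CPM (59.7 to 65.3) against 109 CPM (108 to 111), a log2 ratio of −0.81. Tbx21 was at 22.4 CPM (20.8 to 24.2) against 124 CPM (122 to 125) and Cxcr3 at 0.451 CPM (0.246 to 0.756) against 183 CPM (182 to 185). In cluster 1 alone, with 482 cells of the library labelled Tbx21 KO Treg, Foxp3 was at 46.8 CPM (38.7 to 56.2) against 61.0 CPM in WT, Entpd1 at 43.2 CPM (35.3 to 52.2) against 109 CPM and Tbx21 at 22.0 CPM (16.5 to 28.7) against 124 CPM. Il10 was there at 434 CPM (408 to 461) against 268 CPM in WT and 592 CPM in 762 Tconv cells. Outside these clusters lay 86.4% of the T cells of the library labelled Tbx21 KO Treg. Cluster 5, which is unnamed, held Entpd1 at 29.1 CPM and Il13 at 857 CPM, and cluster 8, led by haemoglobin genes and also unnamed, held Entpd1 at 18.2 CPM. In the CD8-like cluster 12, whose cells the CD4 enrichment and sort should remove, Tbx21 was at 37.4 CPM in 1056 cells of the library labelled Tbx21 KO Treg, 169 CPM in 1417 WT tumor Treg cells and 159 CPM in 2092 Tconv cells.

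**Figure D3:**
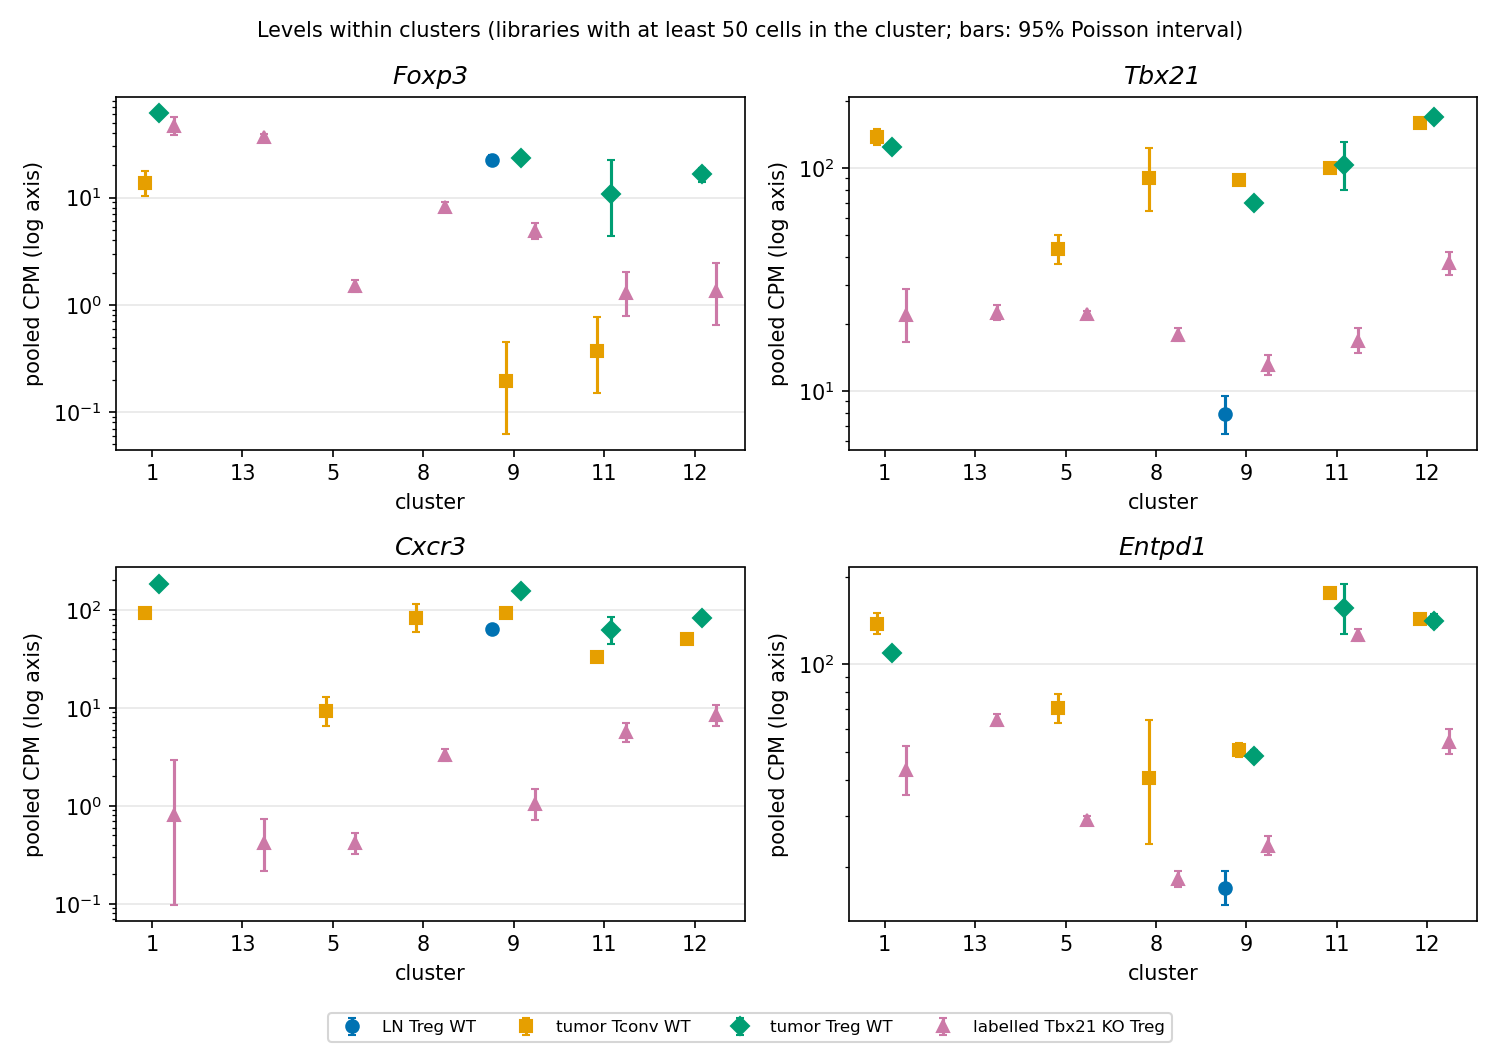
Pooled CPM of 4 genes on log axes in clusters 1, 13, 5, 8, 9, 11 and 12, picked after the data were seen and without clusters 2, 6 and 10, which hold 346, 113 and 117 cells of the library labelled Tbx21 KO Treg, for libraries with at least 50 cells and 1 UMI of the gene in it, with points for libraries and bars for the exact Poisson 95% interval. Tbx21 lay between 13.1 and 37.4 CPM in the 7 clusters shown for the library labelled Tbx21 KO Treg, and Entpd1 in cluster 13 of that library was at 64.1 CPM against 109 CPM in cluster 1 of WT.

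The comparison of WT tumor Treg with LN Treg cells asks how Treg cells in the tumor differ from those of tumor-free lymph nodes. Tissue and tumor inoculation cannot be told apart in this pair. The mix of sexes differed as well, as Xist was almost absent from LN Treg cells. Tumor Treg cells had more of the Th1 programme, effector Treg, immediate early and TCR signal genes, and LN cells more of the naive and central memory genes. Whether the immediate early and TCR signal genes reflect activation in the tumor or the handling of different tissues was not tested. Tbx21 was at 118 CPM against 3.39 CPM (log2 5.11, 5.03 to 5.20), Cxcr3 at 173 CPM against 37.1 CPM (2.22, 2.19 to 2.25) and Ifng at 99.3 CPM against 2.31 CPM (5.42, 5.32 to 5.53). Foxp3 differed little, at 52.3 CPM against 70.2 CPM (−0.43, −0.46 to −0.40). Entpd1 was higher in the tumor, 99.8 CPM against 28.8 CPM (1.79, 1.76 to 1.82), while Nt5e, which encodes the next enzyme on the way to adenosine, was lower, 184 CPM against 295 CPM (−0.68, −0.70 to −0.67).

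Of 6301 genes at 25 CPM 1171 were at least 2-fold apart, 654 higher and 517 lower in the tumor, and 49 of them seen in at least 5% of T cells were over 10 times higher in non-T cells. With mitochondrial and ribosomal protein genes left out of the totals the median of all genes went from −0.07 to −0.30 and the split to 575 higher against 973 lower. In Foxp3 UMI cells 1144 of the 1171 kept their direction at 2-fold, and 1129 did in cluster 1 of the tumor against clusters 3 and 4 of the LN. Equal cluster weights left 1 cluster, the cycling cluster 9 with 754 LN cells, and gave 617 genes. The 12 highest ratios were those of AA467197, Ccl4, Cxcl2, Fosl2, Areg, Cdkn1a, Fosb, Nr4a2, Sytl3, Lilrb4b, Gzmb and Maff, from 5.86 to 9.37. Ccl4, a chemokine gene, was at 666 CPM against 1.12 CPM, and Gzmb, the granule protease, at 767 CPM against 13 CPM. The 12 lowest were Slc28a2b, Dtx1, Gabrr2, Arhgap20, Gata1, Nsg2, Prg4, St8sia1, Evl, St8sia6, Pgpep1l and Il6ra, from −6.10 to −3.87. Dtx1, a Notch pathway regulator, was at 2.71 CPM against 174 CPM, and Il6ra, the interleukin 6 receptor, at 21.9 CPM against 319 CPM.

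Of 19 Th1 genes 17 were higher in the tumor and 0 lower (median 2.74, percentile 100), with Ccl5 at 5.80, Nkg7 at 4.59 and Ccl3, at 531 CPM against 0.103 CPM, at 12.33. Of 24 effector Treg genes 23 were higher (median 2.76, percentile 100). Tnfrsf9, the costimulatory receptor 4-1BB, was at 1713 CPM against 141 CPM (3.61), Icos at 2341 CPM against 449 CPM (2.38) and Lgals1 at 2.20. Of 11 cytotoxic genes 9 were higher (median 3.51), with Klrd1, an NK receptor chain, at 7.24. Of 17 immediate early and heat shock genes 16 were higher (median 2.5), with Junb at 4.03, and of 13 TCR signal genes 8 were higher and 2 lower (median 1.68), with Nr4a1 at 3.33 and Nr4a3 at 3.71. Of 22 glycolysis and hypoxia genes 19 were higher (median 1.66), with Hif1a at 2.72 and Gapdh at 1.46. The percentile of each of these lists was 100. The cell cycle list, 19 of 20 higher (median 1.51), with Top2a at 1.82, was at −0.17 within the cycling cluster 9.

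Of 16 naive and central memory genes 14 were lower and 1 higher in the tumor (median −3.04, percentile 0). Foxp1 was at 98.9 CPM against 584 CPM (−2.56) and Klf2 at −1.73, while Il7r, the interleukin 7 receptor, was the higher member at 1.40. Of 9 Tfh genes 5 were lower and 3 higher (median −1.0, percentile 0.35), with Cxcr5, the follicle homing receptor, at −2.35 and Pdcd1, which encodes PD-1, at 1.32. Of 12 inhibitory receptor genes 7 were higher and 3 lower (median 0.96, percentile 99.99), with Cd274 at 1.12 and Btla at −1.85. Of 16 cytokine genes 11 were higher (median 1.96), including Il10 at 3.71 and Tgfb1 at 1.35, and of 7 measured Th2 genes 5 were higher (median 2.79), including Il1rl1 at 2.79. Both lists were at percentile 100. The chemokine and homing receptor list split, 6 of 20 higher and 8 lower (median −0.10, percentile 32.6), with Cxcr6 at 4.18 and Ccr2 at 3.96 but S1pr1, the egress receptor, at −2.92.

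Of 15 Treg identity genes 5 were higher and 3 lower (median 0.30, percentile 86.5), with Tnfrsf4 at 1.78 and Izumo1r, the folate receptor 4 gene, at −0.68. The adenosine list had 3 of 13 members higher and 5 lower, with a median of −0.31 (percentile 16.1) but a mean of 0.27, and included the purine receptor gene P2rx7 at −1.61 and Dpp4 at −1.10. Of 10 Th17 genes 4 were higher and 3 lower (median 0.19, percentile 76.0), with Rora at 2.85 and Ccr6 at −2.98. Type I interferon genes were mixed, 2 of 16 higher and 5 lower (median −0.17, percentile 49.4; 0.16 in Foxp3 UMI cells), with Isg20 at 1.57 and Ifit1 at −1.19. Of 16 interferon gamma response genes 5 were higher, among them Irf1 at 1.64 and Ifngr1 at 2.45, and the median of 0.17 (percentile 74.9) turned sign when mitochondrial and ribosomal protein genes left the totals. Of 15 lipid metabolism genes 5 were higher and 4 lower, with a median of −0.13 (percentile 53.4) and a mean of 0.44, Srebf2 at −0.81 and Insig1 at 1.01.

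The comparison of WT tumor Treg with WT tumor Tconv cells asks which genes mark the sorted Treg cells inside WT tumors. Treg cells had the Treg identity genes and more Nt5e, and Tconv cells more effector cytokine genes, at similar Tbx21. Foxp3 was at 52.3 CPM against 0.370 CPM (log2 7.14, 6.89 to 7.40) and Tbx21 at 118 CPM against 135 CPM (−0.20, −0.21 to −0.17). Entpd1 was at 99.8 CPM against 75.2 CPM (0.41, 0.38 to 0.43), but at a ratio of 0.00 with equal cluster weights over the 9 clusters that both libraries share. Of the 6892 cells that set these weights, 1529 lay in cluster 2, 1454 in the cycling cluster 9 and 1417 in the CD8-like cluster 12. Cluster 1, where most WT tumor Treg cells lie, had 762 of them. Nt5e was at 184 CPM against 92.0 CPM (1.00, 0.98 to 1.02), Cxcr3 at 173 CPM against 104 CPM (0.73, 0.71 to 0.75) and Ifng at 99.3 CPM against 511 CPM (−2.36, −2.38 to −2.34).

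Of 5724 genes at 25 CPM 295 were at least 2-fold apart, 143 higher and 152 lower in Treg cells, and 22 of them seen in at least 5% of T cells were over 10 times higher in non-T cells. TMM scaling moved the median of all genes from 0.04 to −0.08 and the split to 103 higher against 180 lower, and equal cluster weights left 65 genes. The 12 highest were Foxp3, Lrrc32, Itgae, Klrg1, Frmd5, Ikzf2, Ncmap, Itgb8, Ttn, Tnfrsf9, Ccr2 and Swap70, from 2.5 to 7.14. Itgae, the integrin chain CD103, was at 156 CPM against 4.12 CPM and Klrg1, a receptor of terminally differentiated cells, at 229 CPM against 10.3 CPM. The 12 lowest were Il13, Il21, Il4, Il5, Tgfbr3, Cd40lg, Tnfsf11, Ccl1, Tbc1d4, Csf2, Eomes and St8sia1, from −4.98 to −3.08. Cd40lg, the CD40 ligand of helper cells, was at 20.1 CPM against 191 CPM, Il21 at 3.69 CPM against 77.4 CPM and Eomes, a T-box factor, at 6.13 CPM against 54.5 CPM.

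Of 15 Treg identity genes 13 were higher in Treg cells and 1 lower (median 1.80, percentile 100), with Il2ra at 2.22, Tnfrsf4 at 1.09 and Ctla4 at 0.85. Of 24 effector Treg genes 12 were higher and 1 lower (median 0.52, percentile 100), with Gzmb at 1.65 and Maf at 0.89. Of 19 Th1 genes 13 were lower in Treg cells and 2 higher (median −0.84, percentile 0), with Ccl5 at −1.23, whereas Ccl3 at −1.22 and Ccl4 at −0.66 stood at 0.19 and 0.09 with equal cluster weights. Of 11 cytotoxic genes 7 were lower and 1 higher (median −1.82, percentile 0), with Prf1, the pore-forming protein, at −1.77 and Gzmk at −2.47. Of 16 cytokine genes 11 were lower and 4 higher (median −1.60, percentile 0), the higher ones including Areg at 1.72 and Il10 at 0.99, which was at −0.02 with equal cluster weights. Of 9 Tfh genes 7 were lower (median −1.33, percentile 0), with Pdcd1 at −1.33 and Sh2d1a at −0.94. Of 10 Th17 genes 7 were lower (median −1.34, percentile 0), with Tmem176b at −1.55, and this median was 0.12 with equal cluster weights. Of 7 measured Th2 genes 3 were lower and 1 higher (median −0.13, percentile 7.54).

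Of 16 naive and central memory genes 9 were lower in Treg cells and 4 higher (median −0.86, percentile 0), with Tcf7, a factor of naive and memory T cells, at −2.51 and Satb1 at 0.74. Of 12 inhibitory receptor genes 5 were lower and 1 higher (median −0.32, percentile 0.03), with Havcr2 at −0.73 and Cd200 at −1.47. Of 17 immediate early and heat shock genes 8 were lower (median −0.57, percentile 0), with Fosb at −1.13 and Hspa1b at −0.86. Of 16 type I interferon response genes 6 were higher and 0 lower (median 0.50, percentile 99.98), with Isg20 at 1.52, and with the Treg library held to clusters 1, 3, 4 and 13 4 were higher and 3 lower (median 0.23). Of 16 interferon gamma response genes 7 were higher and 0 lower (median 0.54, percentile 100), with Igtp at 1.47 and Gbp7 at 1.18. Of 20 cell cycle genes 16 were higher (median 0.77, percentile 100), with Cenpa at 0.92 and Mki67 at 0.86. With the Treg library held to clusters 1, 3, 4 and 13 and all Tconv cells kept, which leaves the cycling cluster 9 out of the Treg side by construction, that median was −1.32 and Mki67 stood at −1.01. Of 22 glycolysis and hypoxia genes 3 were higher and 1 lower (median 0.23, percentile 99.6), with Bnip3 at 1.67 and Eno1 at −0.91.

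Other lists stood near 0 in this pair. The adenosine list had 3 of 13 members higher and 1 lower (median 0.14, percentile 82.3), the higher ones being Nt5e, Ada at 1.52 and Adora2b at 1.16, the last at only 2.34 CPM against 1.05 CPM. Of 15 lipid metabolism genes 2 were higher and 3 lower (median −0.06, percentile 10.8), with Fabp5 at 0.75 and Scd2 at −0.78. Of 13 TCR signal genes 2 were higher and 3 lower, with a median of −0.08 (percentile 10.9) and a mean of 0.09, and Nfatc1 at −0.67. Of 20 chemokine and homing receptors 8 were higher and 6 lower (median 0.15, percentile 92.7), with Ccr2 at 2.51 and Itgb1 at −1.66. In this pair the signs of medians this close to 0 are not read.

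Within each library the share of cells with an Entpd1 UMI was compared between cells with and without a Tbx21 UMI, which asks whether Tbx21 and CD39 transcripts meet in the same cells. In WT tumor Treg cells at 2000 UMIs Entpd1 was seen in 20.7% (19.9 to 21.5) of 9215 cells with a Tbx21 UMI and 16.9% (16.5 to 17.2) of those without. In Tconv cells the shares were 14% (13.3 to 14.6) and 12.1% (11.8 to 12.4). In the library labelled Tbx21 KO Treg they were 6.42% (5.31 to 7.69) and 6.58% (6.33 to 6.83), and in LN Treg cells 6.64% (4.05 to 10.2) and 5.48% (5.29 to 5.68), so that no difference was detectable at this depth in either. Split by Cxcr3 instead, the shares were 17.4% and 17.7% in WT tumor Treg cells, 8.82% and 13.3% in Tconv cells, 8.70% and 5.32% in LN Treg cells, and 11% (6.56 to 17.1) of 154 cells and 6.55% in the library labelled Tbx21 KO Treg. Without thinning the gap by Tbx21 was 11.4 percentage points in WT tumor Treg, 12 in Tconv, 9.45 in LN Treg and 3.79 in labelled Tbx21 KO Treg cells. Cells with more UMIs can show both genes more often, so these gaps are not separated from depth. The unthinned split by Cxcr3 in WT tumor Treg cells also opened, to 40.4% and 34.9%.

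**Figure D4:**
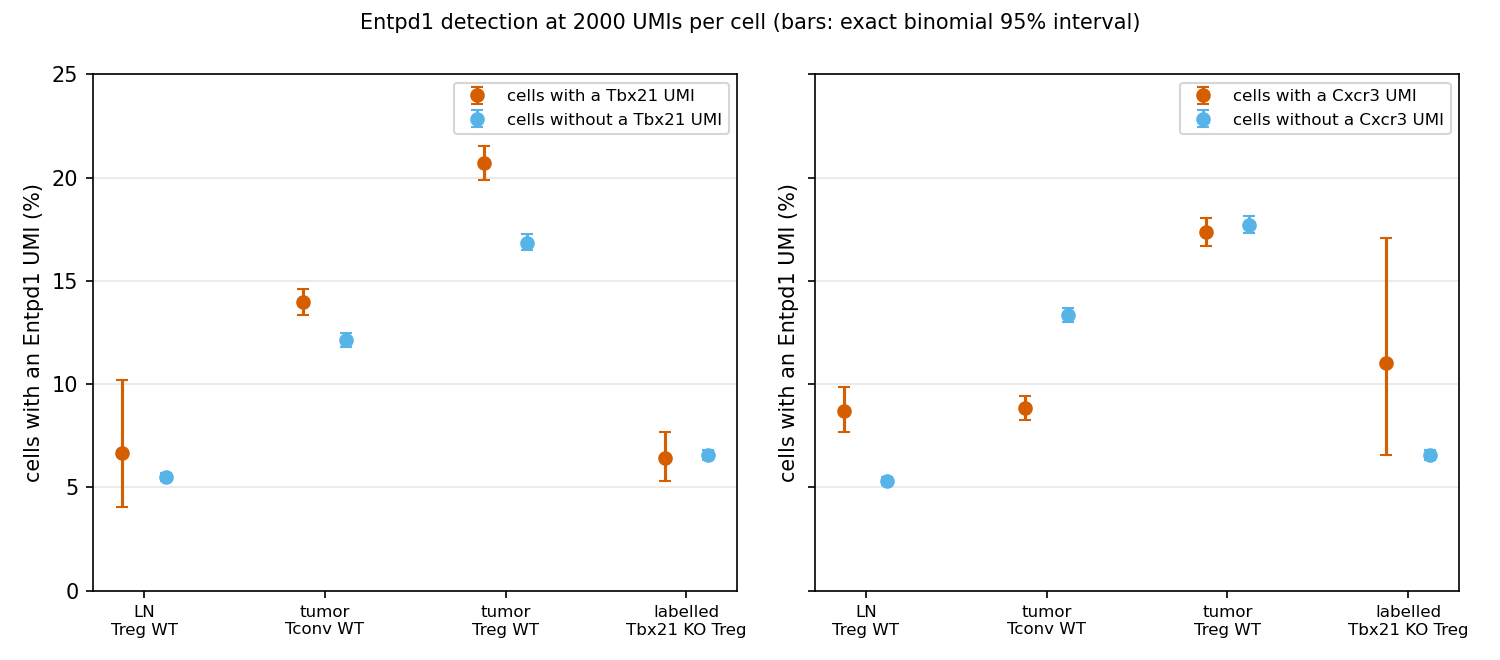
Percent of T cells with an Entpd1 UMI at 2000 UMIs per cell in each library, split by a Tbx21 UMI (left) or a Cxcr3 UMI (right), with bars for the exact binomial 95% interval. The gap by Tbx21 is clear of the intervals in WT tumor Treg (20.7% against 16.9%) and Tconv cells (14% against 12.1%), and the split by Cxcr3 runs the other way in Tconv cells (8.82% against 13.3%).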

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

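For the few Foxp3 UMIs all tests below were chosen only after seeing the results, for the CD8-like cells only the last, and for the macrophage-like cells the bounds were written before the values, except that the subset of cells in the last was chosen after the cluster-wide result. Cell types outside the comparisons were seen above the limit that a count of 0 allows, and this is what singled them out. Hepatoma-like cells made up 20.2% of the cells of the library labelled Tbx21 KO Treg, 0.218% of WT tumor Treg and 0.194% of Tconv cells, with 0 of 52314 cells in LN Treg, which allows up to 0.0057% by a limit of 3 counts of the total and 0.0071% by the exact interval. Macrophage-like cells made up 5.25% of the library labelled Tbx21 KO Treg, 1.43% of WT tumor Treg, 0.567% of Tconv and 0.373% of LN Treg cells. Plasmacytoid dendritic-like cells made up 0.735% of Tconv, 0.474% of labelled Tbx21 KO Treg, 0.0733% of WT tumor Treg and 0.0287% of LN Treg cells. Barcodes removed for mitochondrial UMIs were 13.5% of the library labelled Tbx21 KO Treg, and they too stood in no comparison.

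The T cells of the library labelled Tbx21 KO Treg held few Foxp3 UMIs, at 6.70 CPM against 52.3 CPM in WT. At an equal 2000 UMIs per cell the share of cells with a Foxp3 UMI was 0.161 of the WT share, which argues against depth, and with T cells alone the level was 0.128 of WT, which argues against non-T cells. A swap with the Tconv library is argued against by Foxp3 in the library labelled Tconv, at 0.007 of WT. T cells without Foxp3 beside unchanged Treg cells and a lower level in the Treg cells themselves cannot be told apart, since Foxp3 was 0.619 of WT (0.582 to 0.657) in clusters 1 and 13 but 0.768 (0.634 to 0.923) in cluster 1 alone, on either side of a bound of 0.667 set after the data were seen, and Tconv cells also entered cluster 1, at 13.6 CPM of Foxp3. For the 86.4% of T cells outside clusters 1 and 13, cells from outside the gate and cells that lost Foxp3 cannot be told apart, since no count of YFP or Cre was used and each library stands alone.

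In the CD8-like cluster 12 of the library labelled Tbx21 KO Treg Tbx21 and Cxcr3 were lower than in WT, although the design deletes Tbx21 in Foxp3-expressing cells. RNA from other cells is argued against as the whole cause by the CD3 genes, which it would lower alike. Their log2 ratios there were −0.43 (−0.47 to −0.39) for Cd3e, −0.17 for Cd3d and 0.38 for Cd3g, while Tbx21 was at −2.18. With Cd8a and Cd8b1 included the median was 0.042, but both genes lead the cluster and are no independent check. For misplaced cells, the 963 of 1056 and 1352 of 1417 cells with a Cd8a and a Cd8b1 UMI were taken. In them the log2 ratio of Tbx21 was −2.17, so the lower level held in cells with both CD8 transcripts. They are most of the same cells and both genes lead the cluster, so this cannot decide on misplaced cells. With 37.4 CPM of Tbx21 left, deletion outside Foxp3 cells and lower use of an intact gene cannot be told apart, since the deleted exons are not in the labels.

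The macrophage-like cells of cluster 14 differed between the library labelled Tbx21 KO Treg (2893 cells) and WT tumor Treg (664 cells), and the interferon gamma response was lower, with a median log2 ratio of −1.59 and 18 of 20 genes lower, among them Cxcl9 at −3.47 and Gbp2 at −2.69. More response to interleukin 4 and 13 missed its bound as a whole list, with a median of 0.43, where Arg1 was at 2.99 and Retnla at 1.43 but Ccl22 at −2.37 and Clec10a at −1.05. The macrophage markers were higher (median 1.06, 8 of 9), where thinning by other RNA would lower them. Lyz2, C1qb and C1qc among them lead the cluster, so their level is not independent of how cells were grouped. The T cell transcript Cd3e was at 163 CPM against 282 CPM in WT, so stray T cell RNA may also differ between the libraries. The markers therefore cannot decide on thinning. A different mix of cells or T cell RNA is argued against by cells with at least 3 UMIs of C1qa, C1qb and C1qc and none of Cd3d, Cd3e, Cd3g, Trac or Trbc2, in which the interferon gamma list stood at −1.65, though from only 41 WT cells. The interferon gamma values are those a lower response needs, but all 16 type I interferon response genes were lower as well (median −1.61), so interferon gamma is not singled out, and the genotype that the title and the series design give, the sex of the mice and other differences between single libraries stay open and untested.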

How the results depend on the processing

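The alternatives were written before the data were examined, except clusters 1, 3, 4 and 13, the sets without cluster 5, 8 or 12 or without cells with an Mcpt8 UMI, and Foxp3 UMI cells for the Entpd1 share, which were chosen after seeing the data. Of 270 log2 ratios of named genes at least 1.5-fold apart 249 kept their direction under every one of the 18 alternatives that was run for them (Foxp3 was not taken in Foxp3 UMI cells) and 21 did not, and of 30 such list medians 26 kept it and 4 did not. Many of these genes were named for their ratios in these same data, so few reversals could occur. The minimum of 1000 UMIs and the other clusterings hardly changed the T cells used. These counts are therefore no measure of robustness. The values below are log2 ratios, in the order labelled Tbx21 KO Treg over WT (KO), tumor over LN (LN) and Treg over Tconv (TC). Where not said otherwise the cause was not tested. Genes 2-fold apart in KO, 631 as reported, were 1840 with all cells, 371 in Foxp3 UMI cells, 288 with equal cluster weights, which leave out clusters 5, 8 and 13 with 18473, 10561 and 5054 cells of the labelled Tbx21 KO library, 355 in clusters 1, 3, 4 and 13, and by construction 1026 from 10 CPM and 266 from 100 CPM. In LN, 1171 became 617 with equal weights, 1866 from 10 CPM and 534 from 100 CPM, and in TC 295 became 65, 490 and 112. Entpd1 in KO (−1.49) was −2.12 with all cells, −1.06 in Foxp3 UMI cells, −1.58 without possible mixed droplets, −1.44 at 10% mitochondrial UMIs, −1.29 with TMM, −1.44 without mitochondrial and ribosomal protein genes, −1.58 as per-cell mean, −1.61 at 1000 UMIs, −1.14 with equal weights, −0.81 in clusters 1, 3, 4 and 13, −1.21 without cluster 5 and −1.35 without cluster 8. Tbx21 in KO (−2.50) was −3.37 with all cells, −2.65 in Foxp3 UMI cells, −2.63 at 10% mitochondrial UMIs, −2.30 with TMM, −2.45 without those genes, −2.41 as per-cell mean, −2.37 at 1000 UMIs, −2.27 with equal weights, −2.62 without cluster 5 and −2.46 without cluster 8. The Th1 list in KO (−1.24) was −1.66 with all cells and in Foxp3 UMI cells, −1.34 without mixed droplets, −1.08 at 10% mitochondrial UMIs, −1.04 with TMM, −1.18 without those genes, −1.16 as per-cell mean and at 1000 UMIs, −1.02 with equal weights, −1.63 in clusters 1, 3, 4 and 13, −1.01 without cluster 5, −1.22 without cluster 8 and −1.11 without cluster 12. Entpd1 in LN (1.79) was 1.68 in Foxp3 UMI cells, 1.83 without mixed droplets, 1.85 at 10% mitochondrial UMIs, 1.60 without those genes, 1.84 as per-cell mean, 1.51 with equal weights and 1.89 in clusters 1, 3, 4 and 13. Entpd1 in TC (0.41) was 0.45 without mixed droplets, 0.35 at 10% mitochondrial UMIs, 0.29 with TMM, 0.35 without those genes, 0.55 as per-cell mean, 0.53 at 1000 UMIs, 0.003 with equal weights, 0.54 in clusters 1, 3, 4 and 13 and 0.46 without cluster 12. The gap in Entpd1 share by Tbx21 was 5.07 percentage points (LN Treg), 4.45 (Tconv) and 5.68 (WT tumor Treg) at 4000 UMIs and 2.53 (WT tumor Treg) at 1000 UMIs. Without thinning, where depth is not held equal, it was 9.45 (LN Treg), 12.007 (Tconv), 3.79 (labelled Tbx21 KO Treg) and 11.4 (WT tumor Treg). In the library labelled Tbx21 KO Treg it was −2.35 in clusters 1, 3, 4 and 13 and −3.04 in Foxp3 UMI cells, and in WT tumor Treg 2.60 in Foxp3 UMI cells. Directions reversed in KO for Adora2a (0.04 in Foxp3 UMI cells, 0.048 in clusters 1, 3, 4 and 13), Areg (0.045 and 0.27), Itgae (0.21 and 0.72, 0.24 with equal weights), Gzmk (−0.041 with equal weights, −0.062 in these clusters), Igtp (0.016), Sostdc1 (−0.48), Tcf7 (−0.22, and −0.23 without cluster 8) and the interferon gamma list (0.11) in these clusters, Il10 (−0.025) and Il2ra (−0.21) with all cells, and Nusap1 (0.21) and Top2a (0.00) without cluster 5. Areg and Itgae are among the leading genes of cluster 13, so their values in these clusters are not independent of the grouping. In LN directions reversed with equal weights, which by construction leave only the cycling cluster, for Cenpa (−0.042), Maf (−0.078), Stmn1 (−0.66) and the cell cycle list (−0.17). In TC they reversed with equal weights for Ccl3 (0.19), Ccl4 (0.093), Entpd4 (0.008, and 0.58 at 1000 UMIs), Il10 (−0.023), Stmn1 (−0.23) and the Th17 list (0.12), and in clusters 1, 3, 4 and 13, which by construction leave out cycling Treg cells, for Mcm3 (−0.041), Mki67 (−1.01), Stmn1 (−1.501) and the cell cycle list (−1.32). At other resolutions and with clustering on all genes no ratio or list median left its interval, and the counts of genes 2-fold apart lay between 627 and 631 in KO and at 1171 or 1172 in LN and stayed at 295 in TC, and a minimum of 1000 UMIs removed no cell. No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out.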

Other observations

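In clusters 1 and 13 of the library labelled Tbx21 KO Treg, mostly from cluster 13, Nt5e was at 323 CPM (317 to 329) against 213 CPM (211 to 215) in WT, and Ifng at 11.9 CPM (10.7 to 13.2) against 63.5 CPM (62.4 to 64.6). Il13 was at 27.3 CPM against 0.567 CPM, far below the 857 CPM of cluster 5. At 2000 UMIs it was seen in 4.00% (3.50 to 4.55) of cells of clusters 1, 3, 4 and 13 of the library labelled Tbx21 KO Treg. Hepatoma-like cells of that library showed it in 3.43% (3.10 to 3.79) and macrophage-like cells in 8.09%, so this Il13 is not shown to exceed stray RNA. In the CD8-like cluster 12 Entpd1 was at 54.1 CPM against 141 CPM in WT tumor Treg and 142 CPM in Tconv, while Nt5e was at 201 CPM against 93.9 and 74.8 CPM and Gzmb at 2749 CPM against 2419 CPM in WT tumor Treg. In cluster 11, led by Eomes, Ccl5 and Gzmk, Tbx21 was at 16.9 CPM in 2511 cells of the library labelled Tbx21 KO Treg against 99.7 CPM in 2660 Tconv cells. In the cycling cluster 9 Eomes was at 40.3 CPM against 3.04 CPM in WT tumor Treg.

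In the macrophage-like cluster 14 of the library labelled Tbx21 KO Treg over WT, Chil3, a marker of alternative activation chosen after its value was seen, was at a log2 ratio of 5.51. Mrc1 was at 1.17, Ccl24 at 1.84 and Cd163 at 3.21, while Ciita was at −2.55 and Nos2 at 1.24. Of the 12 interleukin 4 response genes 5 were higher and 3 lower, the latter being Ccl17 (−0.91), Ccl22 (−2.37) and Clec10a (−1.05). The macrophage markers had a median of 1.06 there, near the value of Mrc1.

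The labels give no sex of the pooled mice. Xist was at 147 CPM in the library labelled Tbx21 KO Treg, 85.1 CPM in WT tumor Treg, 107 CPM in Tconv and 0.047 CPM in LN Treg cells. Ddx3y was at 63.1, 125, 114 and 133 CPM and Uty at 8.42, 37.6, 29.2 and 37.9 CPM in the same order, so all libraries held Y chromosome transcripts. Only LN Treg cells lacked Xist almost wholly, so the mix of sexes differed between tumor and LN libraries and is not separated from tissue. Xist was also higher and Ddx3y and Uty lower in the library labelled Tbx21 KO Treg than in WT tumor Treg. A difference in sex mix is thus not separated from that label. The sex chromosome list had a median log2 ratio of −1.36 in the library labelled Tbx21 KO Treg over WT (4 of 5 lower, 1 higher), −0.09 in tumor over LN (mean 1.78) and 0.09 in Treg over Tconv, the last turning sign with TMM scaling.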
